A study of Glycine max with 8 samples.

How the data were processed

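The study measured transcript levels in the aerial tissue of Williams 82 soybean seedlings with Affymetrix Soybean Gene 1.0 ST arrays. Seeds germinated on moist paper under light at 25 degrees, and the seedlings were put fully under deionized water at an age of 4 d, at noon, per the labels. Tissue was harvested after 24 h or 120 h of submergence, and a further group of the latter had 1 d of reoxygenation. For each array 500 ng of total RNA was made into sense-strand cDNA, of which 5.5 µg was fragmented and labelled. The series describes 2 independent biological replicates per treatment and names non-submerged seedlings as the control. The age of the control seedlings at harvest, the slides and the scan dates are not given in the sources used here.

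The deposited values are log2 signals made by the authors with RMA, per the submitters' processing notes. RMA corrects background, applies quantile normalization and summarizes probes per probe set. The software version of RMA and its probe set level are not given in the sources used here. The labels do not state the scale, and log2 was read from the range of the values, whose array medians lay between 2.53 and 2.57. The number of arrays limits the precision. All probe sets were tested as deposited, with no further normalization and no filter. Control probe sets could not be recognised by their IDs or the annotation, so none were left out. A platform annotation gave 1 gene symbol for 3085 probe sets, several for 54 and none for 72851. The 3085 probe sets stand for 2952 genes, of which 788 have an informative symbol or synonym and 2164 are known by a LOC number alone. Of the 3085 probe sets, 3072 had a gene ID found in the RefSeq gene table. A total of 107 genes had more than 1 probe set, and in reoxygenation minus 5 d the probe sets of 1 of these genes were called in opposite directions. For lists, the probe set with the highest mean over all 8 arrays stood for its gene. Probe sets with several symbols or none were counted but not named.

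All 8 arrays entered 1 fit with a mean for each of the 4 groups, made with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with default settings). Then 5 contrasts were tested, namely 1 d minus control, 5 d minus control, 5 d minus 1 d, reoxygenation minus 5 d and reoxygenation minus control. Benjamini-Hochberg adjustment ran over all probe sets within a contrast, and a probe set was called at an adjusted p under 0.05. The median SE of a contrast was 0.227, with 4 residual and 4.23 prior degrees of freedom. The moderated F-test of limma over the 3 contrasts against the control asked how many probe sets differed among the groups. Recovery classes were counted from the calls. Values expected with no effect for comparisons that share arrays came from 20 simulations of unchanged groups. These drew independent normal noise with the moderated variances of the fit, so the simulated covariances depend on those variances. Values for independent lists came from the product of the numbers of calls divided by the number of probe sets. Groups of 2 arrays are too small for a test of other splits of the arrays or for a rule on single deviating arrays.

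Gene lists were tested with camera of limma at a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over 125 pairs of list and contrast (25 lists with at least 5 genes, 5 contrasts). Camera with an estimated correlation and fry were alternatives. With an estimated correlation camera also takes its p from the 4 residual degrees of freedom, far fewer than with the preset correlation. That version has little power after adjustment over 125 pairs. A list call lost there is therefore not evidence that correlation between genes alone removed it. Camera set each list against all probe sets, most of which carry no symbol. In each contrast calls were more frequent among genes with 1 symbol than among all probe sets. A list shift therefore need not set the list apart from other genes with a symbol. Of 36 lists written before the data were examined, to be matched on gene descriptions, 3 matched at least 1 gene, since the annotation holds symbols and no descriptions, and 2 of these could be tested, heat shock proteins and WRKY transcription factors. The list of autophagy and senescence held 3 stay-green genes. None of the genes of the lists of fermentation, hypoxia response and reference genes could be matched. Therefore 26 further lists were written from gene symbols, after the annotation, the distribution of values and the correlations between arrays had been seen but before any comparison of groups. Of these, 23 were large enough to test. With the preset correlation, 52 of the 125 pairs passed. With an estimated correlation 0 passed in camera of limma, where 36 had an unadjusted p under 0.05, against 60 with the preset correlation. With fry 66 passed.

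The named genes followed a rule written before the data were examined. For each contrast these were the 10 probe sets with the largest rise and the 10 with the largest fall among those called, where both arrays of 1 group lay outside the range of the other. The rule asked for an informative gene description, and since the annotation holds none, an informative symbol or synonym was used instead. For each list and contrast the rule added the 2 called members that rose most and the 2 that fell most. The contrasts, tests, thresholds and all alternatives apart from 1 were also chosen before the data were examined.

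The alternatives were quantile normalization applied again, centring each array on its median, leaving out the 25% or the 50% of probe sets with the lowest mean, a mean-variance trend with a robust prior, array weights, the replicate number as a block, leaving out each array in turn, a fit of the 2 groups compared alone, a change of at least 2-fold, an adjusted p under 0.01, and for lists the estimated correlation, fry and the mean of a gene's probe sets. A fit of the probe sets whose IDs start with 11 or 12, which hold all named probe sets, was added after the data were seen. The code was tested on simulated data for 5 d minus control, in which 50 probe sets were changed at each of 4 sizes. These data had the real means and independent normal noise with the moderated variances of the fit, which are less dispersed than the observed ones. It recovered 0% of log2 changes of 0.5, 12% of 1, 96% of 2 and 100% of 3, with 3 false among 107 calls. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.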

Results

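Transcript levels were measured in the aerial tissue of seedlings of the soybean cultivar Williams 82 on 8 Affymetrix Soybean Gene 1.0 ST arrays. The seedlings were grown for 4 d on wet paper at 25 degrees and either not submerged (the control), completely submerged for 1 d, submerged for 5 d, or submerged for 5 d and returned to air for 1 d (reoxygenation). Each of the 4 groups held 2 arrays from independent biological replicates. Each array gave a log2 value per probe set. The array medians lay between 2.53 and 2.57, and the interquartile ranges between 2.73 and 2.91. Pearson's r across probe sets, which are not independent replicates, was 0.9697 to 0.9844 between replicates and 0.9429 to 0.9698 between arrays of different groups. The first principal component held 36.1% of the variance and placed the control (64.01 and 68.35) and the reoxygenation arrays (47.37 and 44.76) on one side, and the 1 d (-27.66 and -24.14) and 5 d arrays (-87.87 and -84.82) on the other. The second held 19.4% and set the reoxygenation arrays (-62.14 and -59.68) apart from the control arrays (33.19 and 34.01). A gene symbol was given for 3085 probe sets, so most called probe sets carry no name here. All changes below are differences of group means on the log2 scale, with the standard error (SE) of the limma fit and 2 arrays per group. For each gene named with a rise or fall among the largest changes, both arrays of one group lay outside the range of the other group. The age of the control seedlings at harvest is not given in the sources used here, and each treatment was harvested at 1 time, so the design does not separate age from treatment. The number of arrays limits the precision of every value.

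**Figure D1:**
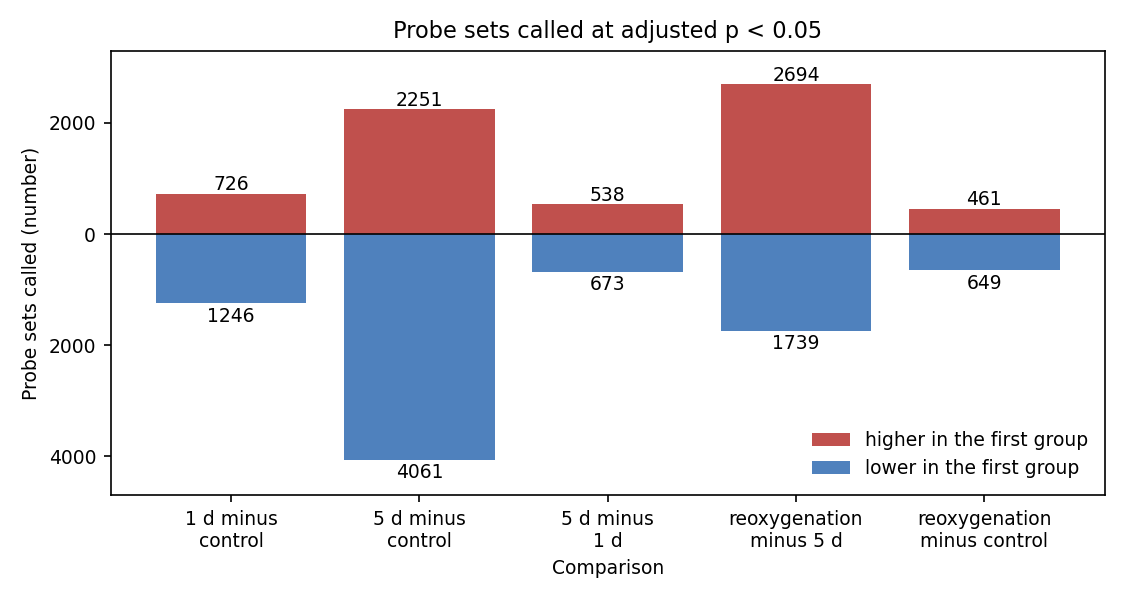
Number of probe sets called higher (upward bars) or lower (downward bars) in each of the 5 comparisons. Lower calls outnumbered higher calls at 1 d (1246 against 726) and at 5 d (4061 against 2251), and higher calls outnumbered lower ones in reoxygenation minus 5 d (2694 against 1739).

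The comparison of 1 d of submergence with the control asked what changed within the first day under water. Of all 2952 genes with 1 symbol, 63 were called higher and 139 lower. Part of the genes listed under vegetative storage, lipoxygenases and jasmonate fell. The vegetative lipoxygenase gene LOX7 went from 5.85 ± 0.64 to 2.35 ± 0.18 (SD, n = 2), a change of -3.50 (SE 0.37). VLXC, another vegetative lipoxygenase, changed by -3.27 (SE 0.23), and LOC547820 (VSPB), which encodes a vegetative storage protein, went from 11.82 ± 0.05 to 8.59 ± 0.33, a change of -3.23 (SE 0.20). Of the 15 genes in the list of vegetative storage, lipoxygenases and jasmonate, 7 fell, 0 rose and 8 did not pass, with a median change of -0.65 (camera adjusted p = 1.58e-09). This list call had adjusted p = 0.0585 with an estimated correlation.

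Some flavonoid genes fell as well. DFR2, which encodes dihydroflavonol reductase, went from 6.11 ± 0.20 to 2.97 ± 0.52 (SD, n = 2), a change of -3.15 (SE 0.28), and F3H, which encodes flavanone 3-hydroxylase, changed by -2.16 (SE 0.31). Of 30 genes of flavonoid and isoflavonoid synthesis, 9 fell and 21 did not pass. The median was -0.53 (camera adjusted p = 1.56e-10, and adjusted p = 0.0585 with an estimated correlation). Glutathione S-transferases, which join glutathione to toxic compounds, included 6 genes that fell among 29, with GSTU41 at -2.43 (SE 0.19) and GSTU38 at -1.94 (SE 0.19). Their median was -0.24 (camera adjusted p = 8.58e-06, and adjusted p = 0.147 with an estimated correlation). Of 14 antioxidant enzymes and alternative oxidases, 2 fell, DHAR4 at -1.61 (SE 0.24) and AOX3 at -1.45 (SE 0.18). A dimmer probe set of DHAR4, with a control mean of 1.01, changed by 0.38 and was not called. The list's median was -0.49 (camera adjusted p = 1.02e-04, and adjusted p = 0.083 with an estimated correlation). Both Kunitz trypsin inhibitor genes called, KTI-2 at -3.17 (SE 0.22) and KTI-3 at -2.05 (SE 0.17), fell. So did the beta-1,3-glucanase gene LOC547748 (SGlu5) at -2.56 (SE 0.18) and the chitinase gene CHIA1 at -1.83 (SE 0.19). The 9 pathogenesis-related and osmotin-like genes held 2 falls and a median of -0.50 (camera adjusted p = 0.0318, and adjusted p = 0.22 with an estimated correlation). Other large falls were those of AG1 at -2.77 (SE 0.19), ODC2 at -2.29 (SE 0.18) and ZFP1 at -2.19 (SE 0.24).

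The 8 translation genes had a median of -0.45 with 0 called (camera adjusted p = 0.00341, and adjusted p = 0.164 with an estimated correlation). The 11 genes of photosynthesis and chlorophyll synthesis held 1 fall, FTRC at -1.21 (SE 0.24), and a median of -0.28 (camera adjusted p = 0.00967, and adjusted p = 0.333 with an estimated correlation). The 17 NAC transcription factors had a median of 0.28 with 0 called (camera adjusted p = 0.0277, and adjusted p = 0.169 with an estimated correlation). Of the 56 WRKY transcription factors, a list fixed before the data were examined, 0 rose and 2 fell, WRKY5 at -1.78 (SE 0.24) and WRKY12 at -1.09 (SE 0.16). Adjusted over the list alone, 1 rose and 3 fell. Of the 5 heat shock proteins, likewise fixed before, 0 were called and 0 adjusted over the list alone. The 3 stay-green genes held 0 calls and 1 fall adjusted over the list alone. AS1, an asparagine synthetase gene, fell by 1.41 (SE 0.20), and the clock gene MYB114 (LCL2) fell by 1.89 (SE 0.18).

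Among the rises at 1 d, GASA7, a member of the gibberellin-regulated GASA peptides, went from 6.08 ± 0.09 to 8.82 ± 0.06 (SD, n = 2), a change of 2.74 (SE 0.17). GASA29 rose by 1.52 (SE 0.24). FAD2-1, which encodes an oleate desaturase, rose in all 5 of its probe sets, by 1.02 to 2.71, with 2.71 (SE 0.21) in probe set 12221330, whose values 2 others share, and 2.52 (SE 0.21) in probe set 12221308. The stearoyl desaturase gene SACPD-C rose by 1.79 (SE 0.34), while FAD3C fell by 1.49 (SE 0.20). The proline-rich protein gene PRP rose by 2.22 (SE 0.27) in probe set 11855184, and XET1, which encodes a xyloglucan endotransglycosylase, rose by 1.47 (SE 0.30). Other rises were those of PC7 at 2.13 (SE 0.33), the peroxidase gene Ep at 2.07 (SE 0.29), the glyoxalase gene GLYI-20 at 1.61 (SE 0.29), and the blue-light receptor gene FKF1 at 1.60 (SE 0.22). The sucrose synthase gene SS rose by 0.96 (SE 0.17), the uricase gene UR9 by 1.43 (SE 0.18) and the receptor kinase gene SARK by 1.06 (SE 0.17).

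With limma, 1972 probe sets were called at 1 d, 726 higher and 1246 lower, and 1672 of them changed at least 2-fold. Unadjusted p lay under 0.05 for 11173. The count was 363 without control replicate 1, 319 without control replicate 2, 643 and 678 without 1 d replicates 1 and 2, and 1300 without either reoxygenation array. Of 42 named changes at 1 d, 16 stayed called whichever array was left out. Without control replicate 1 the calls on PC7 (adjusted p = 0.129), SACPD-C (0.209), GASA29 (0.139), GLYI-20 (0.111), FKF1 (0.0608), F3H (0.0988), DHAR4 (0.116), AOX3 (0.0742), SS (0.18), UR9 (0.0746), SARK (0.128), FAD3C (0.0612), WRKY5 (0.0835), WRKY12 (0.121), XET1 (0.186), FTRC (0.125), AS1 (0.0807) and PRP (0.0615) ended. Without control replicate 2 the calls on ZFP1 (0.0531) and, among the former, all except GLYI-20 ended (0.0532 to 0.282). Without 1 d replicate 1 the calls on Ep (0.0703), SACPD-C (0.156), GLYI-20 (0.133), GASA29 (0.0681), WRKY12 (0.0704), FTRC (0.193), SS (0.118), F3H (0.0553), DHAR4 (0.0886), AS1 (0.0648), UR9 (0.0548), SARK (0.0768) and the lists of photosynthesis (0.0936) and pathogenesis-related genes (0.111) ended. Without 1 d replicate 2 those on Ep (0.0739), SACPD-C (0.136), GLYI-20 (0.112), FKF1 (0.057), GASA29 (0.104), XET1 (0.122), WRKY12 (0.0732), FTRC (0.0972), SS (0.0824), F3H (0.0795), DHAR4 (0.0657), UR9 (0.0505), SARK (0.0817), FAD3C (0.0616) and the NAC list (0.139) ended. Without either reoxygenation array the calls on GLYI-20 (0.0547), XET1 (0.0846), FTRC (0.0807) and SS (0.053) ended, and without either 5 d array that on XET1 (0.0632). A fit of these 2 groups alone ended the calls on PC7 (0.0601), GLYI-20 (0.0823), XET1 (0.11), WRKY12 (0.051), FTRC (0.0766), SS (0.0723) and SARK (0.0534), and centring on medians that on FTRC (0.0505). The pathogenesis-related list was not called after quantile normalization again (0.0666) or without the dimmest 25% (0.185) or 50% (0.261) of probe sets, and without the dimmest 50% neither were photosynthesis (0.104) and translation (0.066).

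The comparison of 5 d of submergence with the control asked what changed after prolonged submergence. Of all 2952 genes with 1 symbol, 172 were called higher and 455 lower. A list whose calls lie near these shares is not set apart from the other genes by its counts. LOC547820 (VSPB) went from 11.82 ± 0.05 to 6.20 ± 0.09 (SD, n = 2), a change of -5.62 (SE 0.20, adjusted p = 1.75e-05), and VSPA, the other vegetative storage protein gene, went from 12.61 ± 0.01 to 7.94 ± 0.22, a change of -4.67 (SE 0.18). AG1 changed by -5.56 (SE 0.19) and LOC547748 (SGlu5) by -5.19 (SE 0.18). CYP93E1, which encodes a cytochrome P450 of soyasapogenol synthesis, went from 9.49 ± 0.04 to 4.50 ± 0.31, a change of -4.99 (SE 0.20). The lipoxygenase gene LOX7 changed by -4.74 (SE 0.37), to a mean of 1.11 that lay below the first quartile of both 5 d arrays (1.47 and 1.44), so the size of its change is limited by the background. VLXC changed by -4.54 (SE 0.23), with GASA34 at -3.95 (SE 0.22), GH at -3.92 (SE 0.17) and the transcription factor gene MYB73 at -3.61 (SE 0.17). Of the 15 vegetative storage, lipoxygenase and jasmonate genes, 8 fell, 0 rose and 7 did not pass, with a median of -1.54 (camera adjusted p = 1.9e-12, and adjusted p = 0.0585 with an estimated correlation).

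Flavonoid and isoflavonoid synthesis held 15 falls and 0 rises among 30 genes at 5 d, with a median of -0.81. DFR2 changed by -3.06 (SE 0.28) and the chalcone isomerase gene CHI3A1 by -2.69 (SE 0.25). This list had camera adjusted p = 1.25e-12, and adjusted p = 0.0585 with an estimated correlation. Of 29 glutathione S-transferases, 7 fell and 0 rose, with GSTU41 at -2.01 (SE 0.19) and GSTU38 at -1.89 (SE 0.19), and a median of -0.43 (camera adjusted p = 5.54e-05, and adjusted p = 0.166 with an estimated correlation). Of 14 antioxidant genes, 6 fell and 0 rose, including SODB at -2.76 (SE 0.34) and SODB2 at -1.78 (SE 0.30), which encode iron superoxide dismutases. Their median was -0.39 (camera adjusted p = 0.00197, and adjusted p = 0.121 with an estimated correlation). Of 11 photosynthesis and chlorophyll genes, 5 fell and 1 rose. The chlorophyll-binding protein gene CAB3 changed by -1.60 (SE 0.18) and the porphyrin synthesis gene HEMB by -1.50 (SE 0.18), while the early light-induced gene ELIP rose by 1.59 (SE 0.28). That list's median was -0.34 (camera adjusted p = 0.00395, and adjusted p = 0.325 with an estimated correlation).

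Seed storage proteins and protease inhibitors held 4 falls among 19 genes at 5 d. KTI-2 changed by -3.48 (SE 0.22) and KTI-3 by -2.47 (SE 0.17), and the list's median was -0.44 (camera adjusted p = 0.00108, and adjusted p = 0.14 with an estimated correlation). Among 30 seed maturation and LEA genes, 6 fell, such as PM22 at -1.41 (SE 0.20), and 2 rose, such as PM29 at 1.42 (SE 0.23). That list was not called (camera adjusted p = 0.0924). Translation genes had 3 falls among 8, led by EF1BGAMMA4 at -1.27 (SE 0.21), and a median of -0.74 (camera adjusted p = 8.49e-04, and adjusted p = 0.14 with an estimated correlation). Fatty acid and glycerolipid genes had 4 falls and 1 rise among 28, with FAD3C at -1.54 (SE 0.20) and a median of -0.44 (camera adjusted p = 0.00733, and adjusted p = 0.137 with an estimated correlation). Of 10 nitrogen genes, 2 fell. The asparagine synthetase gene AS2 changed by -2.37 (SE 0.22) and the glutamine synthetase gene GS1GAMMA2 by -2.21 (SE 0.30). Their list's median was -0.43 (camera adjusted p = 0.0429, and adjusted p = 0.321 with an estimated correlation).

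Genes of lists that were not called as lists, or not tested, also changed at 5 d. The xyloglucan enzyme gene XTH1 changed by -2.86 (SE 0.22) and the expansin gene EXP1 by -2.21 (SE 0.19). The aquaporin gene PIP2-1 changed by -1.57 (SE 0.20), the phytochrome gene PHYA by -1.44 (SE 0.19), the tubulin gene TUBB3 by -1.53 (SE 0.19) and LOC548079 (PCNA), a DNA replication gene, by -2.04 (SE 0.25). The nodulin gene ENOD40B changed by -2.76 (SE 0.24) and PR1-1, a pathogenesis-related gene, by -2.12 (SE 0.21). PEPC17, which encodes a phosphoenolpyruvate carboxylase, changed by -1.58 (SE 0.19), while PPCK1, which encodes a kinase of that enzyme, rose 2.82-fold. Lists not called at 5 d were low-oxygen carbon and amino acid metabolism (2 rose and 3 fell of 16), sugar transport and carbohydrate breakdown (4 rose and 1 fell of 9), GASA peptides (3 rose and 2 fell of 18), wall proteins (2 rose and 3 fell of 13), pathogenesis-related genes (1 rose and 4 fell of 9), auxin response and transport (2 fell of 6), aquaporins (2 fell of 5), root and nodule marker genes (2 rose and 2 fell of 16) and clock and photoreceptor genes (1 rose and 1 fell of 9), with camera adjusted p from 0.136 to 0.657. No gene of the planned lists of fermentation and hypoxia response could be matched, so the low-oxygen list does not stand for those responses. The lists of ferritins (1 fell of 4), chromatin and DNA replication (1 fell of 4) and tubulins with an elongation factor (1 fell of 3) were too small to test. Among pathogenesis-related genes the median was 0.14, while the mean (-0.77) and the test pointed downward. In the list of wall proteins the median (-0.20) and the test pointed downward, while the mean was 0.00202. The aquaporins' median of 0.08 differed in sign from the mean (-0.50) and the test.

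The rises of named genes at 5 d were led by XET1, which went from 3.94 ± 0.14 to 8.29 ± 0.20 (SD, n = 2), a change of 4.35 (SE 0.30, adjusted p = 1.73e-04). The glyoxalase genes GLYI-20 at 3.98 (SE 0.29) and GLYI-6 at 2.56 (SE 0.21), whose enzymes act on methylglyoxal, rose, and 0 of the other 4 genes of that list passed. The list's median was 0.38 (camera adjusted p = 0.0162, and adjusted p = 0.254 with an estimated correlation). GASA7 rose by 3.23 (SE 0.17), Ep by 2.90 (SE 0.29), STP1 by 2.39 (SE 0.24) and PC7 by 2.35 (SE 0.33), and PRP rose by 2.59 (SE 0.26) in probe set 11865065 and by 2.58 (SE 0.27) in probe set 11855184. The small heat shock protein gene HSP17.5-E went from 1.04 ± 0.17 to 4.18 ± 0.17, a change of 3.14 (SE 0.19). Its control mean lay below the first quartile of both control arrays (1.37), so the size of the change is limited by the background. HSP17.5-E was the 1 of 5 heat shock genes called, 5 rose adjusted over the list alone, and the list's median was 0.65 (camera adjusted p = 2.48e-04, and adjusted p = 0.121 with an estimated correlation).

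Of 17 NAC genes, 8 rose and 1 fell, with NAC34 at 1.96 (SE 0.18) and NAC3 at 1.96 (SE 0.23), and a median of 0.85 (camera adjusted p = 7.26e-07, and adjusted p = 0.0585 with an estimated correlation). LOC732579 (DREB2) rose by 2.48 (SE 0.19) and was 1 of 3 rises among 14 ethylene, ERF and DREB genes, whose median was 0.32 (camera adjusted p = 0.0177, and adjusted p = 0.19 with an estimated correlation). Of 56 WRKY genes, 8 rose, such as WRKY8 at 1.52 (SE 0.20), and 4 fell, such as WRKY58 at -1.76 (SE 0.25), while 9 rose and 6 fell adjusted over the list alone. The list as a whole was not called (camera adjusted p = 0.367). SARK at 1.52 (SE 0.17) was the 1 rise of 10 senescence, autophagy and vacuolar protease genes, whose median was 0.41 (camera adjusted p = 0.0236, and adjusted p = 0.169 with an estimated correlation). The 3 stay-green genes held 0 calls, and 1 rise adjusted over the list alone, with a median of -0.00471 and a mean of 0.35. The beta-amylase gene LOC547684 (BMY1) rose by 1.88 (SE 0.17), SWEET34, a sugar transporter gene, by 1.90 (SE 0.37) and SS by 0.95 (SE 0.17).

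With limma, 6312 probe sets were called at 5 d, 2251 higher and 4061 lower, and 4594 changed at least 2-fold. Unadjusted p lay under 0.05 for 15979. The count was 2585 without control replicate 1 and 2381 without control replicate 2. Of 78 named changes, 56 stayed called whichever array was left out. Without control replicate 1 the calls on ELIP (adjusted p = 0.0848), SS (0.0906), PM29 (0.0524), SWEET34 (0.0944) and the nitrogen list (0.0757) ended. Without control replicate 2 those on PPCK1 (0.0507), SODB2 (0.0737), EF1BGAMMA4 (0.0811), ELIP (0.0541), SS (0.0693), PM29 (0.0645), SWEET34 (0.0958) and the senescence list (0.0597) ended. Without 5 d replicate 1 the calls on SWEET34 (0.0638) and on the senescence list (0.0553) ended. Without 5 d replicate 2 those on ELIP (0.0587), SWEET34 (0.0687) and the lists of ethylene factors (0.13), nitrogen (0.0858), fatty acid synthesis (0.0509) and glyoxalase I (0.151, with a median of -0.03) ended. The nitrogen list was not called after quantile normalization again (0.0717), without the dimmest 25% (0.0718) or 50% (0.125) of probe sets, with the mean of each gene's probe sets (0.0533), or among probe sets with IDs starting 11 or 12 (0.0651), the last of these chosen after seeing the data. Without the dimmest 50% the lists of photosynthesis (0.0971), senescence (0.0921) and fatty acid synthesis (0.341) were not called.

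**Figure D2:**
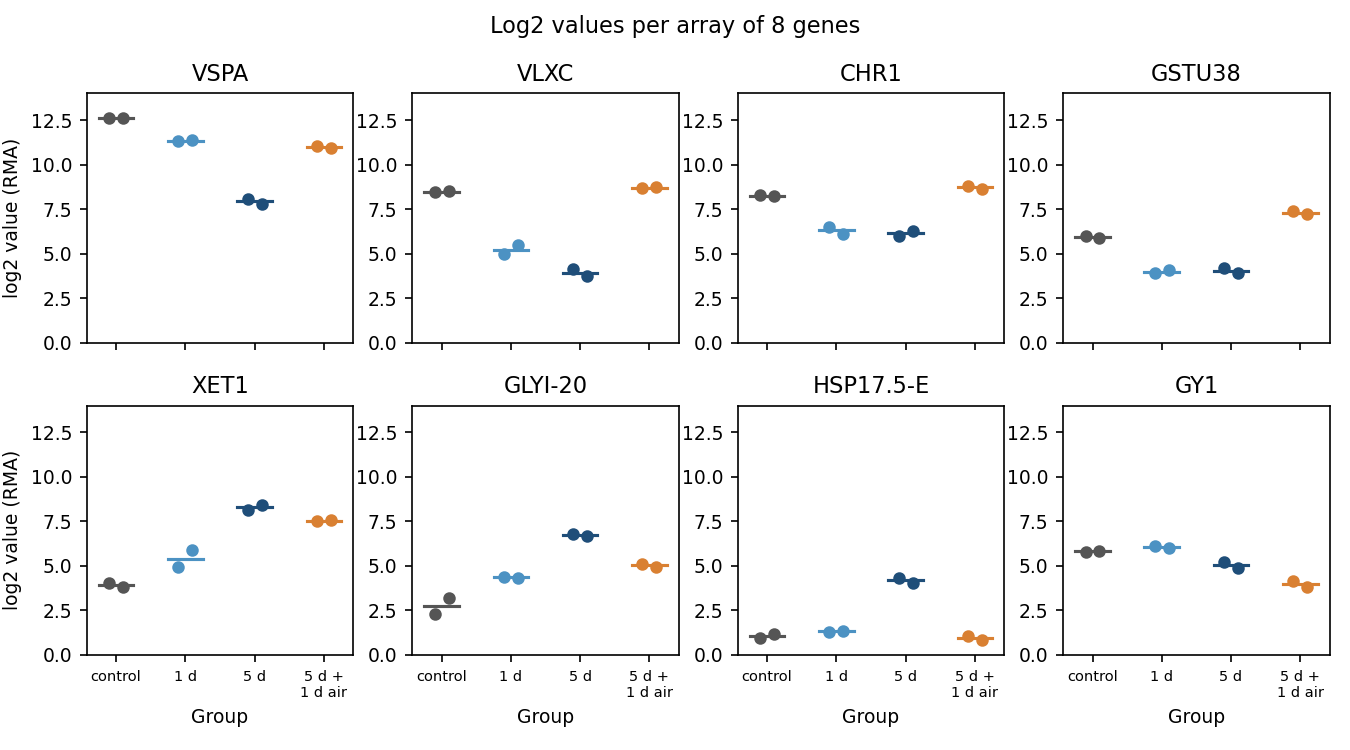
Log2 values of 8 genes, with 1 point per array and a line at each group's mean of 2 arrays, over the 4 groups. VSPA fell to a mean of 7.94 at 5 d, GSTU38 stood at 7.31 after reoxygenation, and GY1 was lowest after reoxygenation (3.98).

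Changes at 1 d and at 5 d largely shared their direction. Both comparisons called 525 probe sets higher and 1036 lower, against 22 and 67 for independent lists, and 3 and 3 in opposite directions. The 20 simulations with shared controls and no effect gave 0 shared calls in each direction, which is no chance value for lists of this length. Across probe sets r was 0.689 against a simulated 0.501, and the covariance was 0.183 against a simulated 0.0345. The covariances differed by 0.148. Parts of the control group would hold 1 array each, so the controls were not split, and part of the excess of shared calls over independent lists may come from the shared controls. The direct comparison of 5 d with 1 d tested the difference itself. Of all 2952 genes with 1 symbol, 55 were called higher and 78 lower at 5 d than at 1 d. VSPA changed by -3.42 (SE 0.18), CYP93E1 by -3.47 (SE 0.20), AG1 by -2.79 (SE 0.19), GASA34 by -2.71 (SE 0.22), LOC547748 by -2.63 (SE 0.18), DAO by -2.55 (SE 0.20), MYB73 by -2.54 (SE 0.17), XTH1 by -2.52 (SE 0.22), LOC547820 by -2.39 (SE 0.20) and GH by -2.25 (SE 0.17). Of 15 vegetative storage, lipoxygenase and jasmonate genes, 5 fell further (median -0.60, camera adjusted p = 6.01e-09, and adjusted p = 0.0585 with an estimated correlation). Flavonoid genes held 1 further fall, CHI1B2 at -1.44 (SE 0.17), and a median of -0.21 (camera adjusted p = 0.00346, and adjusted p = 0.153 with an estimated correlation). Seed storage genes held 1 fall, CG-BETA-1 at -1.07 (SE 0.21), and a median of -0.31 (camera adjusted p = 8.49e-04, and adjusted p = 0.137 with an estimated correlation). Fatty acid genes held 2 falls and a median of -0.17 (camera adjusted p = 0.0483, and adjusted p = 0.19 with an estimated correlation). FAD2-1, higher at 1 d, fell by 1.84 (SE 0.21) from 1 d to 5 d in probe set 12221308, and its 5 probe sets changed by -2.09 to -0.84, 4 of them called.

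Rises from 1 d to 5 d of named genes above the background were led by XET1 at 2.87 (SE 0.30), SWEET34 at 2.46 (SE 0.37), GLYI-20 at 2.38 (SE 0.29), SB100 at 2.01 (SE 0.24), GLYI-6 at 2.01 (SE 0.21), STP1 at 1.95 (SE 0.24), PPCK1 at 1.68 (SE 0.22), the stay-green gene SGR1 at 1.64 (SE 0.31) and MYB114 at 1.61 (SE 0.18). HSP17.5-E rose by 2.86 (SE 0.19) from a 1 d mean of 1.32, below the first quartile of both 1 d arrays (1.464 and 1.435), so the size of its rise is limited by the background. Of 5 heat shock genes, 2 rose and 5 rose adjusted over the list alone, with a median of 0.88 (camera adjusted p = 2.34e-07, and adjusted p = 0.0709 with an estimated correlation). The call on the other of the 2, HSP22.3 at 1.11, ended whichever array was left out. It also ended in limma with a mean-variance trend (adjusted p = 0.0521), with array weights (0.0877) and in a fit of these 2 groups alone (0.136). SGR1 was the 1 stay-green gene of 3 that rose, against 2 adjusted over the list alone. Of 17 NAC genes, 4 rose, such as NAC34 at 1.39 (SE 0.18), with a median of 0.39 (camera adjusted p = 1.16e-06, and adjusted p = 0.0585 with an estimated correlation). The glyoxalase list had a median of 0.64 (camera adjusted p = 0.00309, and adjusted p = 0.19 with an estimated correlation), and the senescence list, with SGR1 as its 1 rise, a median of 0.42 (camera adjusted p = 0.00153, and adjusted p = 0.121 with an estimated correlation). The ethylene, ERF and DREB list, with LOC732579 at 1.59 (SE 0.19), had a median of 0.23 (camera adjusted p = 0.0342, and adjusted p = 0.221 with an estimated correlation). Of 56 WRKY genes, WRKY12 rose by 1.27 (SE 0.16), against 4 rises adjusted over the list alone.

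With limma, 1211 probe sets were called between 5 d and 1 d, 538 higher and 673 lower, and unadjusted p lay under 0.05 for 10371. The count was 617 without either control array, 343 and 300 without 1 d replicates 1 and 2, 625 and 577 without 5 d replicates 1 and 2, and 780 without either reoxygenation array. Of 46 named changes, 15 stayed called whichever array was left out. Without 1 d replicate 1 the calls on GLYI-20 (adjusted p = 0.0616), STP1 (0.057), CHI1B2 (0.0591), WRKY12 (0.0639), NAC34 (0.0535), LOC732579 (0.0571) and the ethylene list (0.102) ended. Without 1 d replicate 2 those on GLYI-20 (0.0648), SB100 (0.0541), STP1 (0.0674), PPCK1 (0.0683), CHI1B2 (0.0557), WRKY12 (0.0648), NAC34 (0.0722) and the lists of ethylene factors (0.0556) and fatty acid synthesis (0.174) ended. Without 5 d replicate 1 the calls on SWEET34 (0.0734) and PPCK1 (0.0593) ended, and without 5 d replicate 2 those on SWEET34 (0.083), NAC34 (0.0565) and the lists of ethylene factors (0.258), fatty acid synthesis (0.195) and glyoxalase I (0.072) ended. The calls on SGR1 and CG-BETA-1 ended whichever array was left out, with adjusted p of up to 0.199 and 0.195. They also ended with array weights (0.0805 and 0.0775), and that on CG-BETA-1 after quantile normalization again (0.0543). A fit of these 2 groups alone ended the calls on XET1 (0.0523), SWEET34 (0.107), SB100 (0.0597), GLYI-6 (0.0552), PPCK1 (0.0901), SGR1 (0.147), MYB114 (0.0663), WRKY12 (0.097), CG-BETA-1 (0.208), CHI1B2 (0.0713), NAC34 (0.0901), LOC732579 (0.0663) and FAD2-1 in probe set 12221308 (0.0662). The fatty acid list was not called after quantile normalization again (0.0644), without the dimmest 25% (0.0544) or 50% (0.138) of probe sets, or among probe sets with IDs starting 11 or 12 (0.0715), and the ethylene list not without the dimmest 25% (0.0514).

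The comparison of reoxygenation with 5 d of submergence asked what changed in the day after the return to air. Of all 2952 genes with 1 symbol, 378 were called higher and 136 lower. Several vegetative lipoxygenase and storage genes rose. LOX7 went from 1.11 ± 0.07 to 6.21 ± 0.67 (SD, n = 2), a change of 5.10 (SE 0.37) from a 5 d mean at the background, VLXC from 3.94 ± 0.29 to 8.71 ± 0.03, a change of 4.76 (SE 0.23), and LOX9 rose by 3.77 (SE 0.17). VLXB rose by 3.53 (SE 0.29) in probe set 12092382, and LOC547820 (VSPB) by 4.24 (SE 0.20). Of the 15 vegetative storage, lipoxygenase and jasmonate genes, 8 rose and 0 fell, with a median of 0.72 (camera adjusted p = 6.74e-08, and adjusted p = 0.066 with an estimated correlation). AG1 rose by 4.78 (SE 0.19), LOC547748 (SGlu5) by 4.69 (SE 0.18), CYP93E1 by 4.69 (SE 0.20) and GH by 3.38 (SE 0.17). PR1-1 went from 3.59 ± 0.14 to 7.15 ± 0.04, a change of 3.56 (SE 0.21), and the polygalacturonase inhibitor gene PGIP fell by 1.19 (SE 0.18). Of 9 pathogenesis-related and osmotin-like genes, 6 rose and 1 fell, with a median of 1.08 (camera adjusted p = 3.19e-06, and adjusted p = 0.083 with an estimated correlation).

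Flavonoid and isoflavonoid synthesis held 16 rises and 0 falls among 30 genes after reoxygenation. CHI1B2 went from 6.43 ± 0.03 to 9.29 ± 0.10 (SD, n = 2), a change of 2.85 (SE 0.17), and the chalcone reductase gene CHR1 rose by 2.59 (SE 0.21). The median was 0.86 (camera adjusted p = 1.25e-12, and adjusted p = 0.0585 with an estimated correlation). Of 29 glutathione S-transferases, 7 rose and 0 fell, with GSTU38 at 3.25 (SE 0.19) and GSTL3 at 3.06 (SE 0.20), and a median of 0.38 (camera adjusted p = 7.07e-07, and adjusted p = 0.137 with an estimated correlation). Of 14 antioxidant genes, 4 rose, the ascorbate peroxidase gene APX2 by 1.67 (SE 0.16) and DHAR4 by 1.15 (SE 0.24) among them (its dimmer probe set changed by -0.25 and was not called), with a median of 0.23 (camera adjusted p = 0.0253, and adjusted p = 0.169 with an estimated correlation). Photosynthesis and chlorophyll genes held 4 rises, with CAB3 at 1.23 (SE 0.18), and 1 fall, ELIP at -2.34 (SE 0.28). Their median was 0.23 (camera adjusted p = 0.0275, and adjusted p = 0.378 with an estimated correlation). The low-oxygen carbon and amino acid list had 2 rises, PEPC17 at 1.72 (SE 0.19) and LOC547724 (GAD) at 0.98 (SE 0.17), 1 fall, PPCK1 at -1.16 (SE 0.22), and a median of 0.36 (camera adjusted p = 0.021, and adjusted p = 0.22 with an estimated correlation). AS2 rose by 2.41 (SE 0.22) as the 1 call of 10 nitrogen genes, whose median was 0.47 (camera adjusted p = 9.03e-04, and adjusted p = 0.164 with an estimated correlation). EF1BGAMMA4 rose by 1.44 (SE 0.21) as the 1 call of 8 translation genes, whose median was 0.52 (camera adjusted p = 0.00126, and adjusted p = 0.143 with an estimated correlation). GASA34 rose by 2.17 (SE 0.22) and GASA27 by 1.92 (SE 0.20), while GASA7 fell by 1.60 (SE 0.17). XTH1 rose by 1.84 (SE 0.22).

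The largest fall of a named gene after reoxygenation was that of SHOOT2, from 6.82 ± 0.05 to 3.13 ± 0.17 (SD, n = 2), a change of -3.69 (SE 0.19). HSP17.5-E went from 4.18 ± 0.17 to 0.93 ± 0.14, a change of -3.25 (SE 0.19), and since the latter mean lay below the first quartile of both reoxygenation arrays (1.42 and 1.40), the size of the fall is limited by the background. It was the 1 of 5 heat shock genes called, 5 fell adjusted over the list alone, and the list's median was -0.65 (camera adjusted p = 1.31e-04, and adjusted p = 0.121 with an estimated correlation). UR9 changed by -2.84 (SE 0.18), SACPD-C by -2.58 (SE 0.34), PRP by -2.40 (SE 0.27) in probe set 11855184, GLYI-6 by -2.33 (SE 0.21), LOC732579 by -2.09 (SE 0.19) and LOC100499895 (DREPP) by -1.95 (SE 0.30). The glyoxalase list held 2 falls, GLYI-20 at -1.70 (SE 0.29) being the other, and a median of -0.68 (camera adjusted p = 0.0353, and adjusted p = 0.314 with an estimated correlation). Of 30 seed maturation and LEA genes, 5 fell and 0 rose, with SBP65 at -2.16 (SE 0.24) and PM29 at -1.48 (SE 0.23), and a median of -0.19 (camera adjusted p = 0.00186, and adjusted p = 0.118 with an estimated correlation). Seed storage genes went both ways, KTI-3 rising by 3.20 (SE 0.17) and KTI-2 by 2.59 (SE 0.22) and CG-BETA-1 falling by 1.18 (SE 0.21), and the list was not called (camera adjusted p = 0.13). Of 56 WRKY genes, 1 rose and 6 fell, such as WRKY55 at -1.36 (SE 0.18), while 4 rose and 9 fell adjusted over the list alone. Of 17 NAC genes, 2 fell and 0 rose (camera adjusted p = 0.0504). The 3 stay-green genes held 0 calls, and 1 fall adjusted over the list alone.

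With limma, 4433 probe sets were called between reoxygenation and 5 d, 2694 higher and 1739 lower, and unadjusted p lay under 0.05 for 13942. The count was 2602 without 5 d replicate 1, and 1681 and 1806 without reoxygenation replicates 1 and 2. Of 61 named changes, 35 stayed called whichever array was left out. Without 5 d replicate 1 the calls on DHAR4 (adjusted p = 0.125), LOC547724 (0.0624), PPCK1 (0.0966), GLYI-20 (0.0615) and the lists of photosynthesis (0.0625) and low-oxygen metabolism (0.11) ended. Without 5 d replicate 2 those on CG-BETA-1 (0.059) and the lists of antioxidants (0.0858) and glyoxalase I (0.18) ended. Without reoxygenation replicate 1 the calls on LOC100499895 (0.0608), LOC547724 (0.0929), PPCK1 (0.0829), CG-BETA-1 (0.0904), PM29 (0.0557), DHAR4 (0.0561), GLYI-20 (0.0644) and the photosynthesis list (0.0889) ended. Without reoxygenation replicate 2 those on LOC100499895 (0.0623), CAB3 (0.0546), LOC547724 (0.0677), PPCK1 (0.124), CG-BETA-1 (0.0782), PM29 (0.0631), DHAR4 (0.163), PGIP (0.0623), GLYI-20 (0.0829), EF1BGAMMA4 (0.057) and the lists of antioxidants (0.101) and glyoxalase I (0.221) ended. Without either control array the call on DHAR4 ended (0.0598), and without 1 d replicates 1 and 2 that on the glyoxalase list ended (0.0545 and 0.0556). A fit of these 2 groups alone ended the calls on LOC547724 (0.0681), PPCK1 (0.0567), CG-BETA-1 (0.0642) and DHAR4 (0.107). The photosynthesis list was not called after quantile normalization again (0.0564) or without the dimmest 25% (0.0669) or 50% (0.108) of probe sets, the antioxidant list not without the dimmest 25% (0.0619) or 50% (0.104), and the low-oxygen list not without the dimmest 50% (0.0577).

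**Figure D3:**
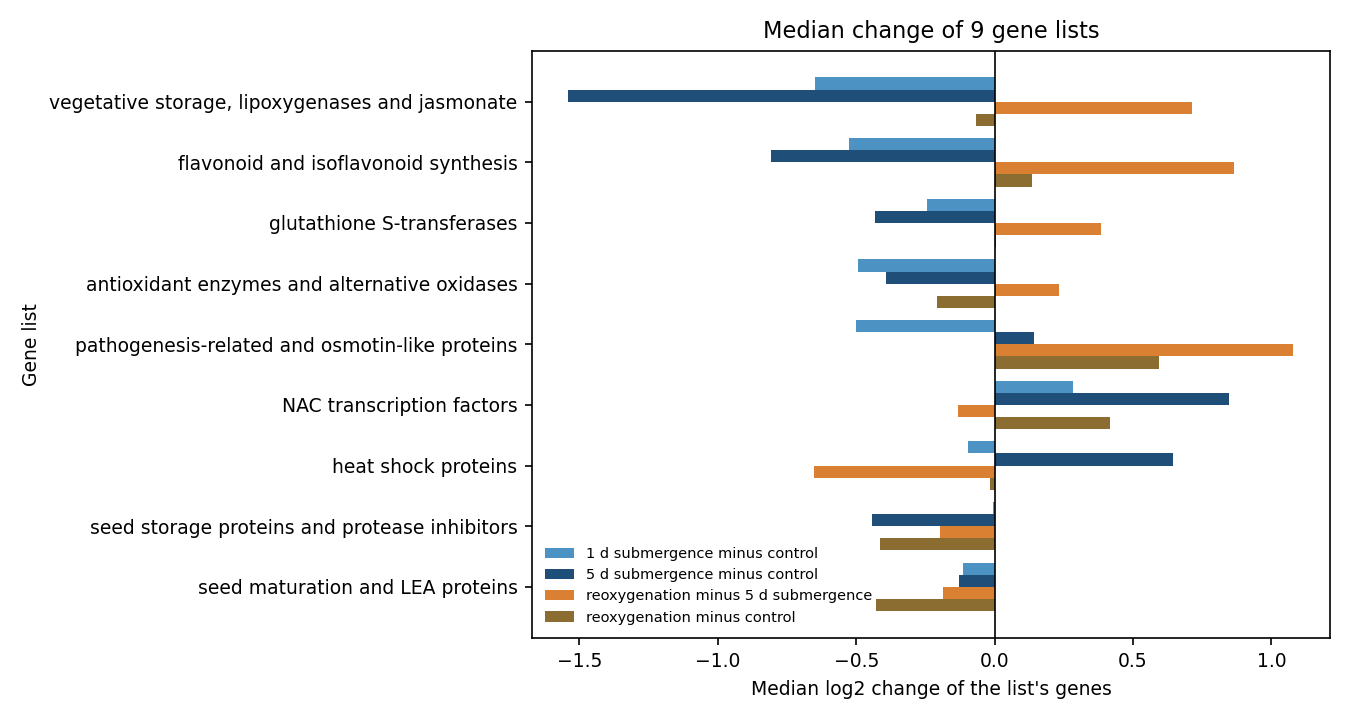
Median log2 change of the genes in 9 lists in 4 comparisons, with 1 bar per comparison. The vegetative storage and flavonoid lists had medians of -1.54 and -0.81 at 5 d and of 0.72 and 0.86 in reoxygenation minus 5 d, and the seed maturation list had -0.43 in reoxygenation minus control.

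The comparison of reoxygenation with the control asked which genes still differed from seedlings never submerged. Of all 2952 genes with 1 symbol, 62 were called higher and 60 lower. The peroxidase gene Ep went from 2.88 ± 0.67 to 7.15 ± 0.05 (SD, n = 2), a change of 4.27 (SE 0.29), and XET1 from 3.94 ± 0.14 to 7.53 ± 0.05, a change of 3.59 (SE 0.30). PC7 rose by 2.79 (SE 0.33), GLYI-20 by 2.28 (SE 0.29), SSTP-2 by 2.28 (SE 0.23), the transporter gene PDR12 by 2.13 (SE 0.29), GASA29 by 2.01 (SE 0.24), PG7 by 1.87 (SE 0.26), NAC34 by 1.86 (SE 0.18) and WIN by 1.84 (SE 0.17). NAC34 was the 1 call of 17 NAC genes, whose median was 0.42 (camera adjusted p = 1.05e-06, and adjusted p = 0.0585 with an estimated correlation). Of 9 pathogenesis-related and osmotin-like genes, 4 rose and 0 fell, with PR1-1 at 1.44 (SE 0.21) and the osmotin-like gene OLPa at 1.42 (SE 0.19), and a median of 0.59 (camera adjusted p = 8.55e-06, and adjusted p = 0.083 with an estimated correlation). The protease gene CYSP2 rose by 1.33 (SE 0.22) as the 1 call of 10 senescence and vacuolar protease genes, whose median was 0.22 (camera adjusted p = 0.00798, and adjusted p = 0.143 with an estimated correlation). Of 18 GASA genes, 2 rose and 1 fell, with a median of 0.16 (camera adjusted p = 0.0342, and adjusted p = 0.449 with an estimated correlation). SS rose by 0.91 (SE 0.17).

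Some seed genes lay below the control after reoxygenation. The conglycinin gene CG-BETA-1 went from 6.91 ± 0.05 to 4.59 ± 0.03 (SD, n = 2), a change of -2.31 (SE 0.21), and the glycinin gene GY1 from 5.82 ± 0.04 to 3.98 ± 0.23, a change of -1.84 (SE 0.20). Of 19 seed storage and protease inhibitor genes, 5 fell and 0 rose, with a median of -0.41 (camera adjusted p = 2.56e-06, and adjusted p = 0.083 with an estimated correlation). Of 30 seed maturation and LEA genes, 3 fell and 0 rose, among them PM12 at -2.23 (SE 0.18) and PGMPM10 at -1.23 (SE 0.17), with a median of -0.43 (camera adjusted p = 2.63e-10, and adjusted p = 0.0585 with an estimated correlation). The largest fall of a named gene was that of CP3 (PM33), from 5.12 ± 0.05 to 2.15 ± 0.12, a change of -2.96 (SE 0.17). SHOOT2 changed by -2.86 (SE 0.19), DFR2 by -2.72 (SE 0.28), DAO by -2.51 (SE 0.20), SODB by -2.48 (SE 0.34), LOX3 by -2.37 (SE 0.20), the starch synthase gene GBSSIa by -2.33 (SE 0.17) and ODC2 by -2.23 (SE 0.18). The vegetative storage, lipoxygenase and jasmonate list held 3 falls, with VSPA at -1.61 (SE 0.18), and a median of -0.07 (camera adjusted p = 0.0275, and adjusted p = 0.22 with an estimated correlation). Its median was 0.01 after quantile normalization was applied again, where the call ended (0.0692). Flavonoid genes held 2 falls, DFR2 and W1 at -1.89 (SE 0.31), and were not called as a list (camera adjusted p = 0.581), with a median of 0.14 and a mean of -0.09.

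Fatty acid and glycerolipid genes had a median of -0.18 in reoxygenation minus control (camera adjusted p = 0.0143, and adjusted p = 0.143 with an estimated correlation), with SACPD-C at -1.77 (SE 0.34) as the 1 fall of 28. Photosynthesis and chlorophyll genes had 0 calls and a median of -0.14 (camera adjusted p = 0.0353, and adjusted p = 0.403 with an estimated correlation). Of 56 WRKY genes, 1 rose, WRKY8 by 1.19 (SE 0.20), and 3 fell, such as WRKY6 at -1.42 (SE 0.21), while 1 rose and 4 fell adjusted over the list alone. That list's median of 0.04 differed in sign from its mean (-0.06) and its test (camera adjusted p = 0.76). Of 5 heat shock genes and of 3 stay-green genes, 0 were called and 0 adjusted over the list alone. The heat shock list's median was -0.02, while its mean (0.00524) and its test (camera adjusted p = 0.952) pointed upward.

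With limma, 1110 probe sets were called between reoxygenation and the control, 461 higher and 649 lower, and unadjusted p lay under 0.05 for 9023. The count was 164 and 176 without control replicates 1 and 2, and 242 and 236 without reoxygenation replicates 1 and 2. Of 43 named changes, 13 stayed called whichever array was left out, those of Ep, XET1, SSTP-2, NAC34, WIN, CP3, SHOOT2, DAO, LOX3, GBSSIa, CG-BETA-1, ODC2 and PM12. Without control replicate 1 the calls on PC7 (adjusted p = 0.0873), PDR12 (0.113), GASA29 (0.0918), PG7 (0.108), SODB (0.123), WRKY8 (0.206), WRKY6 (0.166), SS (0.282), GY1 (0.0642), PGMPM10 (0.143), VSPA (0.0765), W1 (0.153), PR1-1 (0.149), OLPa (0.118), CYSP2 (0.108), SACPD-C (0.215) and the GASA list (0.256) ended. Without control replicate 2 those on DFR2 (0.059), the photosynthesis list (0.134), the fatty acid list (0.109) and, of the former, all except PDR12, W1 and the GASA list (0.0683 to 0.291) ended. Without reoxygenation replicate 1 the calls on GLYI-20 (0.0881) and, of those named for control replicate 1, all except GY1 and the GASA list (0.0518 to 0.217) ended. Without reoxygenation replicate 2 the calls on GLYI-20 (0.0675), PC7 (0.0675), PDR12 (0.0764), GASA29 (0.0761), WRKY8 (0.0773), WRKY6 (0.0606), SS (0.179), GY1 (0.0533), PGMPM10 (0.115), VSPA (0.0627), W1 (0.128), PR1-1 (0.128), OLPa (0.0557), CYSP2 (0.173) and the lists of photosynthesis (0.137), vegetative storage (0.082) and GASA peptides (0.106) ended. Without either 1 d array the calls on SS (0.0646), WRKY8 (0.0525), W1 (0.0531), CYSP2 (0.0558) and SACPD-C (0.0922) ended, and without either 5 d array those on SS (0.0565) and SACPD-C (0.0561). A fit of these 2 groups alone ended the calls on GLYI-20 (0.0515), WRKY8 (0.0683), WRKY6 (0.0547), SS (0.0798), W1 (0.0765), CYSP2 (0.0806) and SACPD-C (0.11), and quantile normalization again that on SACPD-C (0.0562). The photosynthesis list was not called after quantile normalization again (0.0564), without the dimmest 25% (0.0779) or 50% (0.254) of probe sets, with the mean of each gene's probe sets (0.0538) or by fry (0.0764). Without the dimmest 25% or 50% the lists of vegetative storage (0.0619 and 0.161) and fatty acid synthesis (0.0554 and 0.232) were not called. Neither were the senescence list without the dimmest 50% (0.0622) and the GASA list by fry (0.11).

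The recovery counts asked how many of the changes at 5 d turned back after the return to air. Of 2251 probe sets higher at 5 d, 1169 (51.9%) fell after reoxygenation, and 1084 of these were not called against the control. Of 4061 probe sets lower at 5 d, 1843 (45.4%) rose after reoxygenation, and 1738 of these were not called against the control. Still called in the direction of 5 d were 210 of the higher (9.33%) and 466 of the lower probe sets (11.5%), XET1 and NAC34 among them. Many probe sets called at 5 d neither turned back by a call nor stayed called. A probe set not called against the control need not have returned to it. The smallest called change was 0.868 in reoxygenation minus control, against 0.655 at 5 d. Called past the control on its other side were 46 of the higher and 26 of the lower, against 19 and 25 for independent lists. The count for the lower probe sets thus lay near that value. GSTU38 and PR1-1, lower at 5 d, stood above the control by 1.36 (SE 0.19) and 1.44 (SE 0.21), and these calls ended without control replicate 1 (adjusted p = 0.11 and 0.149), control replicate 2 (0.133 and 0.147), reoxygenation replicate 1 (0.113 and 0.119) and reoxygenation replicate 2 (0.0816 and 0.128). Called after reoxygenation against the control and in neither direction at 5 d were 225 higher and 137 lower probe sets. Independent lists would give 52 and 144 turned back. The 20 simulations of unchanged groups gave 0, which is no chance value for lists of this length. The 5 d changes and the changes from 5 d to reoxygenation, which share the 5 d arrays, had r of -0.729 against a simulated -0.501 and a covariance of -0.231 against a simulated -0.0345. The 5 d and reoxygenation changes from the control had r of 0.474, below a simulated 0.5, and a covariance of 0.117, above a simulated 0.0344. The covariances differed by 0.0824. Leaving out 1 array at a time gave 566 and 580 of the higher and 893 and 837 of the lower probe sets turned back without control replicates 1 and 2. Without reoxygenation replicates 1 and 2 the numbers were 530 and 539 higher and 763 and 813 lower, and without 5 d replicate 1 1101 of the lower turned back. Still called were 40 and 44 of the higher and 73 and 75 of the lower without the control replicates, and 52 and 46 of the higher and 108 and 105 of the lower without the reoxygenation replicates. The F-test of limma called 6089 probe sets (8.01%) as differing among the 4 groups. That count was 2960 and 2868 without control replicates 1 and 2, and 3682 and 3760 without reoxygenation replicates 1 and 2.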

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

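The tests on dim probe sets, on seedling age and on seed-derived tissue were chosen only after the result was seen, and those on normalization and on held-out arrays were planned beforehand.

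A group of genes and lists stood out because the effects at 1 d and 5 d differed by a test of the difference itself, 5 d minus 1 d. The genes were taken only from those that the rule named for 1 d or 5 d minus control, on the same arrays. They are therefore not a full account of the genes that differed, and DAO, for example, is not among them. In log2 units the difference was upward for XET1 (2.87), SWEET34 (2.46), GLYI-20 (2.38), GLYI-6 (2.01), STP1 (1.95), PPCK1 (1.68), MYB114 (1.61), LOC732579 (1.59), SBP65 (1.49), NAC3 (1.45), NOD33 (1.43), NAC34 (1.39), WRKY12 (1.27) and LOC547684 (1.00). It was also upward for HSP17.5-E (2.86), whose size is limited by the background, since its 1 d mean lay below the first quartile of both 1 d arrays. It was downward for CAB3 (-0.98), TUBB3 (-1.15), PEPC17 (-1.20), VLXC (-1.27), AUX28 (-1.29), LOC548079 (-1.29), AS2 (-1.36), ENOD40B (-1.37), PIP2-1 (-1.37), PHYA (-1.51), PR1-1 (-1.62), EXP1 (-1.65) and FAD2-1 (-1.84 and -2.09 in 2 probe sets). It was further downward for GH (-2.25), LOC547820 (-2.39), XTH1 (-2.52), MYB73 (-2.54), LOC547748 (-2.63), GASA34 (-2.71), AG1 (-2.79), VSPA (-3.42) and CYP93E1 (-3.47). Among lists the median differences were 0.88 for heat shock proteins, 0.64 for glyoxalase I, 0.42 for senescence and vacuolar proteases, 0.39 for NAC factors and 0.23 for ethylene, ERF and DREB genes. They were -0.17 for fatty acid synthesis, -0.21 for flavonoid synthesis, -0.31 for seed storage proteins and -0.60 for vegetative storage and lipoxygenases. None of these lists passed with an estimated correlation. Leaving out 1 array ended many of these calls. Those on CAB3 (adjusted p = 0.0722 to 0.161), PEPC17 (0.0543 to 0.134), AUX28 (0.0585 to 0.166), LOC548079 (0.0519 to 0.199) ENOD40B (0.0612 to 0.153), VLXC (0.0595 to 0.157) and LOC547684 (0.0664 to 0.142) ended whichever array was left out. Those on TUBB3 (0.0596 to 0.118), NAC3 (0.05 to 0.116) and SBP65 (0.0621 to 0.123) ended without any 1 of the control, 1 d and 5 d arrays, and those on AS2 (0.071 to 0.13) and PIP2-1 (0.056 to 0.11) without any 1 of the 1 d and 5 d arrays. Without 1 d replicate 2 the calls on PHYA (0.0674), PR1-1 (0.0609), EXP1 (0.059) and NOD33 (0.0547) ended, and without 5 d replicate 1 those on PHYA (0.0517) and PR1-1 (0.0589). A fit of these 2 groups alone ended the calls on CAB3, PEPC17, SBP65, NAC3, AUX28, EXP1, AS2, PR1-1, NOD33, ENOD40B, PIP2-1, PHYA, VLXC, LOC547684, LOC548079 and TUBB3 (0.0643 to 0.193), and array weights those on CAB3, SBP65, NAC3, AUX28, AS2, ENOD40B, VLXC, LOC547684 and LOC548079 (0.0507 to 0.0746). The report gives the other gene calls that ended.

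At 5 d, 35.7% of the probe sets called against the control were higher. If values left uneven between arrays were the whole cause, evening them would bring the share near 50%. With quantile normalization applied again the share reached 41.4%. Its SD over fits without 1 array was 2.28, but these fits share most of their arrays, so this SD understates the spread of the share. Unevenness may account for part of the pattern, and whether it is the whole cause is left open. The dimmer 50% of probe sets held 841 of the 6312 calls. Even were all of these lower, the share without them would be at most 41.1%, a bound set by their small number alone. The observed share without them was 34.3%, and the planned fit without the dimmest 25% gave 35.1%. These 2 shares argue against dim probe sets as the whole cause. A larger number of falls than rises under water stays open as a hypothesis, as does seedling age, which was not tested for this share.

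Of the probe sets called at 5 d, 47.7% were called in the opposite direction after reoxygenation. Choosing probe sets on the 5 d arrays and measuring the return from the same arrays could make such a pattern. With 1 of the 5 d arrays held out of the choice, 83.6% to 87.7% of the probe sets called with the other array moved back from the held-out array, which argues against this as the whole cause. The median return from held-out replicates 1 and 2 was 0.784 and 0.843 in log2 units. Their median changes from the control at 5 d were larger, 1.26 and 1.3, though the control arrays also entered the choice. A response to the return to air is a candidate explanation, as a hypothesis. Were the control the youngest group, a steady course with age would carry the 5 d changes on. Of the probe sets called at 5 d, 1169 of the higher and 1843 of the lower turned back, while 6 and 3 were called further the same way. Of those that turned back, 1084 and 1738 were not called against the control, which need not mean a full return. Selection on the shared 5 d arrays may raise the numbers turned back and lower those called further, so these counts do not decide. The shares moving back from the held-out arrays are free of this selection. Were the control the youngest group, these shares argue against a steady course with age as the whole cause. A course with age that turns was not tested, and the age of the control at harvest is not given.

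After reoxygenation 5 of 19 seed storage and inhibitor genes and 3 of 30 seed maturation genes were called lower than in the control, of which only CG-BETA-1 and PM12 stayed called whichever array was left out, and both list calls ended with an estimated correlation (adjusted p = 0.083 and 0.0585). Of 7 storage and inhibitor genes with a control mean above 5, 6 changed downward and KTI-3 upward (0.73). A smaller share of seed-derived tissue that lowers all members alike would give equal falls. The 6 called members of both lists above that mean changed by -1.21 (GY2, not called in a fit of the 2 groups alone, adjusted p = 0.0578) to -2.31 (CG-BETA-1). The gap of 1.098 (SE 0.274) between these extremes was larger than the test allowed for equal falls. The extremes were picked after their values were seen, so the gap does not decide, and this explanation stays open. Under seedling age each member would fall from time to time, and 0 of the 8 called members rose by over 2 SE between successive times, which decides nothing since they were chosen for being lower. Seedling age, tissue share and treatment cannot be told apart for these genes, since each treatment was harvested at 1 time and the age of the control at harvest is not given.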

How the results depend on the processing

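The fit of the probe sets whose IDs start with 11 or 12 was chosen after seeing the data, and all other alternatives here were planned. None reversed a called direction: of 4577 values for named gene changes 3904 stayed called and 673 lost the call, 542 of these by leaving out an array, and of 979 for list shifts 859 stayed called and 120 lost it. Of the calls tested here, those that are printed and that these alternatives ended are named beside the results, and those ended by the replicate block below. Of 52 list calls quantile normalization again ended 6, leaving out the dimmest 25% ended 9 of 49 that could be tested, and leaving out the dimmest 50% ended 15 of 46. Of 270 named gene calls the fit of the 2 groups alone ended 74, array weights 16 and quantile normalization again 7. The causes were not tested unless stated. With a mean-variance trend and robust prior the numbers called were 3075 (against 1972) for 1 d minus control, 2087 (1211) for 5 d minus 1 d and 1798 (1110) for reoxygenation minus control, with 329 (210) of the higher and 717 (466) of the lower 5 d changes still called after reoxygenation. With array weights they were 712 (1211) for 5 d minus 1 d and 1948 (1110) for reoxygenation minus control, with 739 (466) of the lower still called. At an adjusted p under 0.01, a stricter threshold by construction, they were 557 (1972) at 1 d, 2754 (6312) at 5 d, 320 (1211) for 5 d minus 1 d, 1654 (4433) for reoxygenation minus 5 d, 281 (1110) for reoxygenation minus control and 2411 (6089) for the F-test. There 460 (1169) of the higher and 683 (1843) of the lower turned back, and 63 (210) and 121 (466) were still called. A fit of the 2 groups compared alone, with fewer arrays by construction, gave 1064 (1972) at 1 d, 188 (1211) for 5 d minus 1 d, 1955 (4433) for reoxygenation minus 5 d and 732 (1110) for reoxygenation minus control. Of 52 list shifts, 0 passed in camera of limma with an estimated correlation, where 36 had an unadjusted p under 0.05, and 66 pairs passed by fry. The version with an estimated correlation also rests on 4 residual degrees of freedom, so the lost calls do not show the effect of correlation alone. Leaving out 1 array at a time, with the lone array assumed to vary like the other groups, gave 319 to 1833 at 1 d, 2381 to 5815 at 5 d, 300 to 780 for 5 d minus 1 d, 1681 to 3899 for reoxygenation minus 5 d, 164 to 1138 for reoxygenation minus control and 2868 to 4816 for the F-test. The turned back numbered 530 to 1054 of the higher and 763 to 1657 of the lower, the still called 40 to 209 and 73 to 430, and list shifts 45 to 52. Quantile normalization applied again changed the share of higher calls from 36.8% to 44.2% at 1 d and from 35.7% to 41.4% at 5 d, and it turned the median of the vegetative storage list in reoxygenation minus control to 0.0112 (adjusted p = 0.0692). With the replicate block the 5 contrasts gave 1450, 5641, 874, 3733 and 901. It ended 28 of 270 named gene calls and 1 list call, among those printed SACPD-C (0.0573), XET1 (0.0555) and FTRC (0.0723) at 1 d, the nitrogen list (0.0605) at 5 d, SGR1, HSP22.3, CG-BETA-1, CAB3, AUX28, ENOD40B and LOC548079 (0.0621 to 0.0808) in 5 d minus 1 d, and SS (0.077), CYSP2 (0.0534) and SACPD-C (0.078) in reoxygenation minus control. Outside these 270 it also ended those on VLXC (0.0685) and LOC547684 (0.0556) in 5 d minus 1 d and on SCAM-1 (0.0584) in reoxygenation minus 5 d. Over all probe sets, replicate differences correlated between groups at -0.0248 to 0.0312, so no strong pairing by replicate number was seen. A pairing that touches part of the probe sets is not excluded by this measure. Control probe sets could not be recognised, so keeping or leaving them out was not run. With 200 changed probe sets simulated, a log2 change of 1 was recovered in 12% of cases. The deposited values held far more changes, which eases the adjusted threshold, and the smallest called change at 5 d was 0.655.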

Other observations

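A block of 8209 probe sets whose IDs share their leading digits held no gene symbol. At 5 d against the control their median change was 0.19, and 109 were called, 103 of them higher. From 5 d to reoxygenation their median change was -0.17, and 66 were called, 62 of them lower.

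The 5 calmodulin genes were grouped after gene values had been seen, as 1 of 6 gene families tested in 5 comparisons. After reoxygenation against 5 d, SCAM-1 rose by 0.76 (SE 0.18) and SCAM-3 by 1.48 (SE 0.20), and the family's median was 0.67 (camera adjusted p = 0.045, and adjusted p = 0.846 with an estimated correlation). The call on SCAM-1 ended whichever array was left out (adjusted p = 0.0583 to 0.201), with quantile normalization again (0.0545), with array weights (0.0548) and in a fit of the 2 groups alone (0.131), while that on SCAM-3 stayed. The other families and comparisons were not called.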
